A study of Arabidopsis thaliana with 6 samples.

How the data were processed

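The series holds RNA-seq of Arabidopsis thaliana seedlings, with 3 samples of the genotype cnd1-3 and 3 of Col-0, grouped by the genotype in the labels. Per the labels, mRNA was purified with oligo-dT beads, libraries were made with an ABclonal mRNA-seq kit and sequenced on an MGISEQ-T7 as read pairs of 150 bp. The age of the seedlings, the growth conditions and the strandedness of the libraries are not given in the sources used here. Nothing in the labels says that the samples of a genotype were separately grown plants, so all p-values measure the spread between these samples.

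The table used here was deposited by the authors as FPKM per gene and sample, that is, reads scaled to gene length and to the reads assigned to genes, with no further scaling between samples. The submitters' processing notes name HISAT2, featureCounts, Subread and DESeq2 and the TAIR10 build; versions, settings and roles are not given in the sources used here. The table has 32948 genes in 6 columns, 9967 of them at 0 in every sample, with 133 plastid, 152 mitochondrial and 115 with identifiers that are not Arabidopsis locus names. Gene names, exon lengths and coordinates came from the TAIR10.1 annotation, which names 32548 of the genes and lacks the plastid and mitochondrial identifiers of the table. FPKM times exon length gave whole reads, within a tolerance of 0.01, for 99.34% to 99.37% of the values above 0 in each sample, and 140 genes gave none at the annotated length. The recovered depth was 22303431, 22125814 and 23081866 reads for cnd1-3 and 30455907, 26309769 and 23290031 for Col-0. Of 61 plastid genes in the lists, 60 were matched to the annotation by length.

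The main test was limma 3.58.1 in R 4.3.3, with an intensity trend in eBayes, on log2 of FPKM plus 0.5, for the 17096 genes with a mean FPKM of at least 0.5 over the 6 samples. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Fold changes are on this log2 scale, so that they are drawn toward 0 at low levels, and means are FPKM with the SD over 3 samples. Before the data were examined, 25 gene lists with 418 loci were fixed. Lists with at least 5 tested members were compared with all other tested genes by limma's camera at an inter-gene correlation of 0.01, adjusted over 19 lists. Each list was also counted with p-values adjusted over the list alone. The named genes followed a rule fixed with the lists. It took the 10 largest rises and the 10 largest falls among called nuclear genes whose groups do not overlap. From each list it took up to 4 called members with the largest change, or the 2 with the highest mean where none was called. Genes named outside the rule were chosen after seeing the data, and the text says so. For genes with few reads, fold differences come from recovered reads over each group, with a floor of 3 reads where none was seen and a 95% exact binomial interval otherwise. Intervals and floors cover counting error only.

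The procedure was tested on simulated data made from this table, with 17121 genes tested. It found 88% of 50 genes raised 2-fold, 78% of 50 lowered 2-fold, 100% of 50 raised 4-fold and 94% of 50 lowered 4-fold. Of 16903 unchanged genes 0.124% were called, a list with all members raised passed, and 0 of 19 unchanged lists were called. The simulation drew each gene independently, with the same spread for genes of similar level. It therefore cannot show how often the list test calls unchanged lists whose genes vary together.

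The alternatives tried were pseudocounts of 0.1 and 1, no minimum level, a minimum of 2 FPKM, median-ratio scaling, quantile normalization and rescaling to nuclear genes. Further ones were eBayes without trend or with robust fitting, library weights, the replicate number as a block, a test against a log2 fold change of 0.58, camera with an estimated correlation, limma's fry and leaving out each sample in turn. Alternatives chosen after seeing the data were limma's voom on recovered reads, reads thinned to the shallowest library, removal of the trend with GC and length per sample, and that removal together with the block. Further gene lists, chosen after seeing the data, are tested only in the closing observations. Reads recovered this way are not the authors' count table, and no count model was the main test. The genes without Arabidopsis locus names were tested but not named. Plastid genes are named by the symbols of the fixed lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the figures.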

Results

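Messenger RNA was sequenced from seedlings of the thale cress Arabidopsis thaliana, in 3 libraries of the mutant line cnd1-3 and 3 of Col-0, the wild type. The series title ties CND1 to the stability of the nuclear and the chloroplast genome. The comparison asks how transcript levels in the mutant differ from those in the wild type. The 3 cnd1-3 libraries held 22303431, 22125814 and 23081866 reads assigned to genes, and the 3 Col-0 libraries held 30455907, 26309769 and 23290031. Log2 expression correlated across genes at 0.989 to 0.992 between libraries of the same genotype and at 0.974 to 0.98 between genotypes. The first principal component carried 56.7% of the variance and placed the cnd1-3 libraries between -24.05 and -22.8 and the Col-0 libraries between 19.06 and 30.66. The name CND1 was not matched to a locus in the sources used here, so no targeted gene was read as a check of the genotype labels. The labels do not say whether the libraries of a genotype came from separately grown plants.

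In cnd1-3 almost no reads were assigned to MAF5 and MAF4, adjacent MADS-box genes related to the floral repressor FLC. MAF5 (AT5G65080, chromosome 5, 25997504 to 26002619 in the TAIR10.1 annotation) averaged 0.0245 ± 0.0212 FPKM (SD, n = 3) in cnd1-3 and 14.9 ± 3.76 in Col-0, from 2 and 1432 reads in all. That is a 604-fold lower read share in the mutant, with a 95% exact counting interval of 167 to 4990. MAF4 (AT5G65070, 25992193 to 25996202) averaged 0.0545 ± 0.048 FPKM in cnd1-3 and 3.82 ± 1.32 in Col-0, from 6 and 488 reads. That is a 68.6-fold difference, with an interval of 31.3 to 188. QQS (AT3G30720, chromosome 3, 12349047 to 12349933), an Arabidopsis-specific gene involved in starch accumulation, rose from 12.6 ± 3.64 to 96.5 ± 5.88 FPKM. On the log2 scale of FPKM plus 0.5, limma gave -4.85 for MAF5 (SE 0.17, adjusted p = 1.35e-05), -2.91 for MAF4 (SE 0.24, adjusted p = 0.00044) and 2.92 for QQS (SE 0.17, adjusted p = 0.000181). FLC (AT5G10140), named after its values were seen, lay below the minimum level for testing. It had 0 reads in cnd1-3 and 74 in Col-0 (22 to 29 per library), which is at least 20.8-fold lower in the mutant. With no minimum level its log2 fold change was -1.36 (SE 0.08, adjusted p = 0.00129). The neighbouring MAF2 and MAF3 and the unlinked MAF1 were also named after their values were seen. MAF2 and MAF3 had log2 fold changes of 0.13 and -0.18 (adjusted p = 0.399 and 0.144), and MAF1 fell from 10.4 ± 0.361 to 6.9 ± 0.649 FPKM (-0.56, SE 0.09, adjusted p = 0.00599). SOC1, a floral activator that FLC represses and likewise named after its values were seen, rose from 16.2 ± 1.11 to 24.8 ± 1.61 FPKM (0.60, SE 0.08, adjusted p = 0.00302). In total 11 genes with at least 10 reads in each Col-0 library had at most 3 reads over the 3 cnd1-3 libraries, MAF5 and FLC among them.

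**Figure D1:**
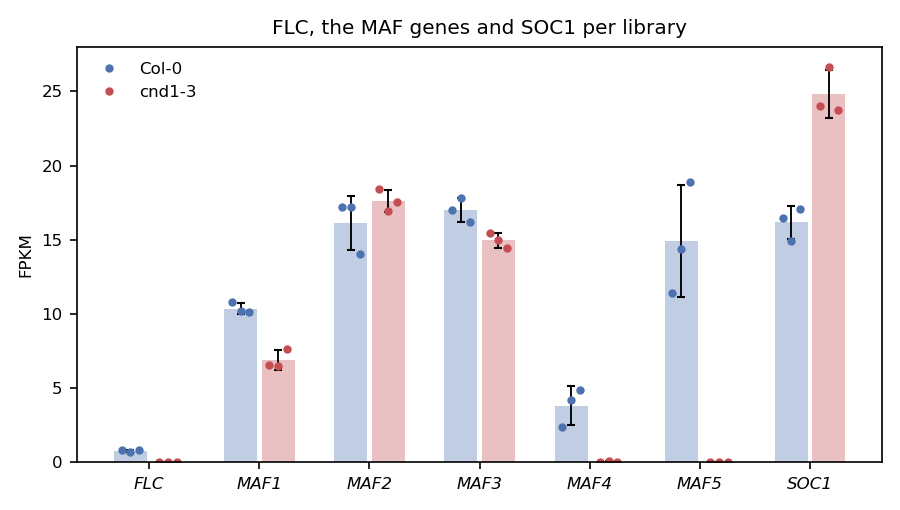
FPKM of FLC, MAF1 to MAF5 and SOC1 in each library (points), with the mean (bar) and SD (n = 3) of Col-0 (blue) and cnd1-3 (red). The cnd1-3 means of FLC, MAF4 and MAF5 lie at 0, 0.0545 and 0.0245 FPKM, and that of SOC1 lies above Col-0, at 24.8 against 16.2.

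Several of the other large falls were in transcription factor genes that respond quickly to stress. ORA47 (AT1G74930), an AP2/ERF factor of the jasmonate pathway, fell from 37.7 ± 16.6 to 1.37 ± 0.648 FPKM (log2 fold change -4.30, SE 0.37, limma adjusted p = 0.000479). CBF1 (AT4G25490), an activator of cold-response genes, fell from 6.84 ± 2.49 to 0.402 ± 0.206 FPKM (-2.98, SE 0.28, adjusted p = 0.000596). ZAT12 (AT5G59820, given as RHL41 in the annotation), a zinc finger protein of oxidative and light stress, fell from 19.9 ± 6.35 to 2.15 ± 0.701 FPKM (-2.93, SE 0.25, adjusted p = 0.000488). The nudix hydrolase gene NUDT4 (AT1G18300) fell from 56 ± 22 to 6.01 ± 0.905 FPKM (-3.05), and AT4G29780, annotated as a nuclease, from 17.1 ± 10.9 to 1.32 ± 0.384 (-3.03). The methyl esterase gene MES8 (AT2G23590) fell from 7.46 ± 1.65 to 0.162 ± 0.113 FPKM (-3.58), and RTFL12 (AT4G13395), which codes for a small polypeptide of the ROTUNDIFOLIA-like family, from 9.02 ± 3.2 to 0.406 ± 0.389 (-3.41). AT1G64795, an uncharacterized gene, had 2 reads in cnd1-3 and 98 in Col-0, a 41.3-fold difference with a 95% exact counting interval of 11.1 to 346. ORA47 and AT1G64795 each overlap another annotated gene on the opposite strand, and the library kit is not stated to keep the strand, so their reads may include some of that gene. The calls of these 10 falling genes, MAF5 and MAF4 included, held in the alternatives in which each was tested, treat not among them, with no adjusted p above 0.0244, which was that of AT4G29780. MAF4 lay below the minimum of 2 FPKM and was not tested there.

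The other large rises were smaller than that of QQS. AT4G22390, annotated as an F-box associated protein, rose from 0.47 ± 0.0271 to 3.17 ± 0.0856 FPKM (log2 fold change 1.92, SE 0.12, limma adjusted p = 0.0002), and AT4G07940, annotated as a putative CWC22-like protein, from 0.862 ± 0.243 to 4.64 ± 1.41 (1.89, SE 0.23, adjusted p = 0.00177). The beta-glucosidase gene BGLU11 (AT1G02850) rose from 2.7 ± 2.68 to 12 ± 6.22 FPKM (2.17, SE 0.52), PHI-1 (AT1G35140) from 2.07 ± 0.974 to 11.2 ± 8.97 (1.98, SE 0.51) and the vacuolar cation exchanger gene CAX3 (AT3G51860) from 0.886 ± 0.881 to 4.46 ± 1.77 (1.94, SE 0.42). The aldo-keto reductase gene AKR4C8 (AT2G37760), the dark-induced gene SEN1 (AT4G35770), AT1G50040 and the transcription factor gene DREB26 (AT1G21910) rose by 1.88, 1.81, 1.79 and 1.76, with SEs of 0.37, 0.46, 0.37 and 0.42. Without Col-0 replicate 2 the adjusted p of these 7 genes lay above the threshold, at 0.115 for BGLU11, 0.101 for PHI-1, 0.0807 for CAX3, 0.0567 for AKR4C8, 0.134 for SEN1, 0.0671 for AT1G50040 and 0.105 for DREB26. Of these genes BGLU11, CAX3, SEN1, PHI-1 and DREB26 also lost the call without cnd1-3 replicate 3 (adjusted p = 0.0847, 0.063, 0.0713, 0.0772 and 0.0696) and without Col-0 replicate 1 (0.0856, 0.0635, 0.107, 0.107 and 0.0893). The same held without cnd1-3 replicate 1 for BGLU11, PHI-1 and AT1G50040 (0.0569, 0.0725 and 0.0608) and without cnd1-3 replicate 2 for BGLU11, CAX3 and SEN1 (0.0629, 0.0659 and 0.0654). With no minimum level BGLU11, PHI-1, CAX3, SEN1 and DREB26 did not pass (0.0702, 0.0822, 0.0516, 0.0813 and 0.0708), nor did BGLU11, PHI-1, SEN1 and DREB26 without the intensity trend (0.0604, 0.0706, 0.0684 and 0.0605) or with robust fitting (0.0607, 0.0714, 0.0709 and 0.0609).

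**Figure D2:**
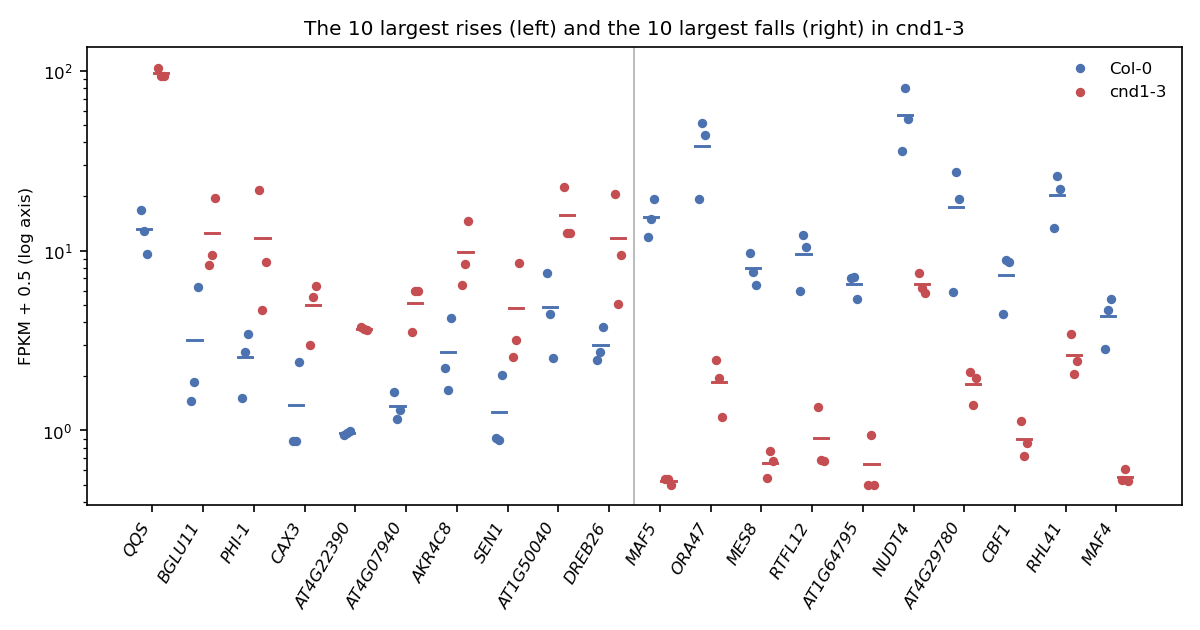
FPKM plus 0.5 (log axis) of the 10 genes with the largest rises, left of the line, and the 10 with the largest falls, right of it, in each library of Col-0 (blue) and cnd1-3 (red), with short lines at the group means. No cnd1-3 point of any gene lies among its Col-0 points, and the 3 MAF5 points of cnd1-3 lie at the bottom of the axis, where FPKM is close to 0.

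Across the transcriptome, 1896 of 17096 tested genes changed between the genotypes (11.1%), 598 of them higher and 1298 lower in cnd1-3. A change of at least 2-fold on the log2 scale of FPKM plus 0.5 was found for 338 of them, 80 higher and 258 lower. An unadjusted p under 0.05 was found for 4893. The values of the genotypes did not overlap in 33.9% of the tested genes, where chance alone gives 10% for 3 against 3 libraries. The lower genes were 68.5% of the calls with the FPKM as deposited, 54.3% after median-ratio scaling, 50.5% after quantile normalization and 53.4% with the GC and length trend removed. Among the calls of at least 2-fold those shares were 76.3%, 72.3%, 66.1% and 69.5%. Without cnd1-3 replicate 1, 2 or 3 the number of changed genes was 906, 1027 or 1166, and without Col-0 replicate 2 it was 909. Tested against a log2 fold change of 0.58 with limma's treat, 107 genes passed, 15 higher and 92 lower.

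No gene of the DNA damage response list was called higher in cnd1-3. Of 14 tested DNA damage response targets, 3 fell, 0 rose and 11 did not pass limma's test, and 3 fell when adjusted over the list alone. RAD17, a checkpoint gene, fell from 2.38 ± 0.164 to 1.47 ± 0.0562 FPKM (log2 fold change -0.55, SE 0.12, limma adjusted p = 0.0205). TSO2, a ribonucleotide reductase subunit gene, fell from 51.8 ± 5.32 to 36.4 ± 3.77 (-0.50, SE 0.10, adjusted p = 0.0167), and BRCA1, a gene of recombination repair, from 2.66 ± 0.315 to 1.8 ± 0.143 (-0.46, SE 0.12, adjusted p = 0.0477). A higher level was called for 0 of the 14, where 5 had an unadjusted p under 0.05 in either direction, and limma's voom on recovered reads also called 3 lower and 0 higher. The CDK inhibitor genes SMR5 and SMR7, named after their values were seen, lay below the minimum level: SMR7 averaged 0.0214 FPKM in cnd1-3 and 0.0212 in Col-0, and SMR5 was listed at 0 in all 6 libraries. As a set the list did not pass (camera adjusted p = 0.493). Of the 14 log2 fold changes 10 lay below 0 and 4 above, up to 0.45. The simulation measured recovery of single genes at 2-fold and 4-fold only, so smaller rises may have been missed. Both RAD17 and TSO2 overlap another annotated gene, on the opposite and on the same strand. The call of RAD17 held only without Col-0 replicate 1 (adjusted p = 0.0357) among the 6 fits that each left out a library, where its highest adjusted p was 0.0644. That of BRCA1 held only without Col-0 replicate 3 (0.0481), with a highest value of 0.137, and it was also lost in 5 other alternatives, up to 0.0934 under quantile normalization. TSO2 lost its call without Col-0 replicate 2 (0.0569), where 0 of the list passed.

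Of 23 tested genes of homologous recombination, RAD50 rose from 5.59 ± 0.22 to 7.44 ± 0.772 FPKM (log2 fold change 0.38, SE 0.10, limma adjusted p = 0.0383), BRCA1 fell and 21 did not pass. Adjusted over the list alone 0 passed, with 5 at an unadjusted p under 0.05, and voom called 1 higher and 1 lower (camera adjusted p = 0.79). The median of that list, -0.09, was above 0 under quantile normalization, at 0.04. RAD50 kept its call only without cnd1-3 replicate 3 (adjusted p = 0.0364) when libraries were left out in turn, with a highest value of 0.122, and BRCA1 only without Col-0 replicate 3 (0.0481). With no minimum level RAD50 and BRCA1 did not pass (0.0665 and 0.0778). Of 20 tested genes of end joining and excision repair, XRCC4, a cofactor of the DNA ligase of end joining, fell from 12.8 ± 1.05 to 5.37 ± 1.35 FPKM (-1.21, SE 0.16, adjusted p = 0.00302). RAD50 and XRCC4 each overlap another annotated gene on the opposite strand. The list as a set did not pass (camera adjusted p = 0.635). Adjusted over the list alone, 1 member was lower. The set test for that list pointed up, while its median of -0.01 and mean of -0.03 lay below 0, and the median was above 0 under median-ratio scaling (0.05), quantile normalization (0.12) and removal of the GC and length trend (0.06).

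Among genes of DNA replication and the cell cycle only TSO2 passed the test. It was 1 of 21 tested replication genes, fell also when adjusted over the list alone, and lost its call without Col-0 replicate 2 (adjusted p = 0.0569). Without Col-0 replicate 3 the replication list had 2 lower genes. It did not pass as a set (camera adjusted p = 0.424). In the G2/M list 0 of 18 tested genes changed by limma's test, with 0 at an unadjusted p under 0.05 and 0 by voom. CDC20.1 averaged 4.8 ± 2.16 FPKM in cnd1-3 and 5.74 ± 2.37 in Col-0 (limma adjusted p = 0.677), and CDC20.2 averaged 2.12 ± 0.705 and 2.67 ± 0.661 (camera adjusted p = 0.635). In the list of CDK inhibitors 0 of 10 tested genes changed, with 3 at an unadjusted p under 0.05 and 0 by voom. KRP1, a gene of this list, averaged 34.8 ± 2.95 and 37.1 ± 5.67 FPKM and SMR1, which overlaps another gene on the opposite strand, 17.3 ± 0.86 and 20.4 ± 1.87 (camera adjusted p = 0.493). Both of these lists also gave 0 calls when adjusted over the list alone.

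Nuclear genes for organelle DNA maintenance changed in both directions. Of 19 tested members 1 rose and 2 fell, and adjusted over the list alone 2 rose and 3 fell. RADA, a gene of organellar recombination, rose from 7.02 ± 0.796 to 9.58 ± 0.0618 FPKM (log2 fold change 0.43, SE 0.09, limma adjusted p = 0.0233). POLGAMMA1, a gene of the organellar DNA polymerases, fell from 13.1 ± 1.29 to 9.78 ± 1.26 (-0.41, SE 0.11, adjusted p = 0.0488), and OSB2, which codes for a single-stranded DNA binding protein of plastids, from 26.3 ± 1.98 to 20.4 ± 1.22 (-0.36, SE 0.08, adjusted p = 0.0258). The set test pointed up without passing (camera adjusted p = 0.635), with a median of 0.06 and a mean of -0.01. POLGAMMA1 overlaps another gene on the same strand. RADA, POLGAMMA1 and OSB2 each lost the call in 4 of the 6 fits that left out a library, with highest values of 0.079, 0.142 and 0.0817. RADA kept it without Col-0 replicates 2 and 3 (0.0266 and 0.0406), POLGAMMA1 without cnd1-3 replicate 2 (0.0377) and Col-0 replicate 3 (0.0324), and OSB2 without Col-0 replicates 1 and 3 (0.0473 and 0.0318). In 6 other alternatives POLGAMMA1 also lost it, among them median-ratio scaling (0.0547) and quantile normalization (0.0601).

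Genes of the plastid genome that serve gene expression were lower where they changed. Of 20 tested members 3 fell, 0 rose and 17 did not pass, and 4 fell when adjusted over the list alone. The ribosomal protein genes RPL14 and RPL16 fell from 18.5 ± 1.75 to 11.5 ± 1.19 FPKM (log2 fold change -0.66, SE 0.10, limma adjusted p = 0.005) and from 46.5 ± 4.21 to 33.7 ± 3.01 (-0.46, SE 0.09, adjusted p = 0.0179), and the RNA polymerase subunit gene RPOB from 24.3 ± 3.5 to 17.1 ± 1.96 (-0.49, SE 0.12, adjusted p = 0.0321). Of 36 tested plastid-encoded photosynthesis genes PSBT, a photosystem II subunit gene, alone rose. It went from 7.7 ± 1.62 to 11.8 ± 1.11 FPKM (0.60, SE 0.15, adjusted p = 0.035), and 0 genes passed when adjusted over the list alone. Of the 36, 12 had an unadjusted p under 0.05, and voom called 0 higher and 1 lower. Without Col-0 replicate 3, 4 of them were lower, and without Col-0 replicate 1, 1 was. Of 21 tested nuclear genes for plastid transcription the sigma factor gene SIG2 alone rose, from 90.3 ± 2.66 to 110 ± 4.48 FPKM (0.28, SE 0.06, adjusted p = 0.0251), also when adjusted over the list alone. These 3 lists did not pass as sets (camera adjusted p = 0.0885, 0.218 and 0.0853). The gene expression list passed under median-ratio scaling (0.0285), without cnd1-3 replicate 1 (0.0497), without Col-0 replicate 3 (0.0173) and with the replicate block. The nuclear list did so under median-ratio scaling (0.0285), without cnd1-3 replicate 3 (0.00712) and without Col-0 replicate 2 (0.0257). It also passed with the replicate block, alone or with the GC and length trend removed. The libraries were made from poly(A)-selected RNA, and most plastid transcripts carry no lasting poly(A) tail, so these values come from a part of the plastid RNA. RPOB lost its call without cnd1-3 replicates 1 and 3 and Col-0 replicates 1 and 2 (adjusted p = 0.0892, 0.0888, 0.0664 and 0.0918), and RPL16 without Col-0 replicates 1 and 2 (0.0553 and 0.0696). PSBT lost its call without each cnd1-3 library and Col-0 replicate 2 (0.0603, 0.0919, 0.0978 and 0.0751) and in 4 other alternatives, up to 0.208 with voom, and SIG2 without cnd1-3 replicates 1 and 2 and Col-0 replicate 2 (0.0868, 0.0941 and 0.0731).

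Tetrapyrrole synthesis genes, which serve chlorophyll and heme production, were higher in cnd1-3 as a set by camera at its preset correlation (adjusted p = 0.00626). The same list had an adjusted p = 0.896 with an estimated correlation, 0.158 by fry and 0.116 under quantile normalization. Splits of the 6 libraries that mix the genotypes also gave called lists by camera, up to 9 against 2 for the genotypes. The set call alone therefore does not tie this list to the genotype. Of 17 tested members 2 rose, 0 fell and 15 did not pass, and the same numbers held when adjusted over the list alone. PORA, a protochlorophyllide oxidoreductase gene, rose from 15.8 ± 2.95 to 27.9 ± 1.91 FPKM (log2 fold change 0.81, SE 0.12, limma adjusted p = 0.00507), and GUN5, which codes for a subunit of magnesium chelatase, from 284 ± 24.6 to 372 ± 6.77 (0.39, SE 0.08, adjusted p = 0.0144). The list as a whole had 13 of 17 log2 fold changes above 0 and a median of 0.08. GUN5 lost its call without cnd1-3 replicate 1 (adjusted p = 0.0601).

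Of 25 tested nuclear photosynthesis genes 2 fell and 0 rose, also when adjusted over the list alone, and both code for light-harvesting chlorophyll proteins of photosystem II. LHCB1.1 fell from 3569 ± 804 to 1532 ± 254 FPKM (log2 fold change -1.21, SE 0.17, limma adjusted p = 0.00373) and LHCB1.2 from 9827 ± 459 to 7545 ± 488 (-0.38, SE 0.09, adjusted p = 0.0301). The LHCB1 genes are nearly identical in sequence, so the split of reads between them is uncertain. LHCB1.2 kept its call only without Col-0 replicate 1 (adjusted p = 0.0434) among the fits that left out a library, and under median-ratio scaling, quantile normalization, removal of the GC and length trend and no minimum level it did not pass (0.115, 0.462, 0.0846 and 0.28). The list as a set did not pass (camera adjusted p = 0.635).

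Genes of oxidative stress and organelle retrograde signalling held the largest changes of the fixed lists, in both directions. Of 12 tested members 5 fell and 2 rose, and adjusted over the list alone 5 fell and 5 rose. ZAT12, WRKY40, ZAT10 and ERF5, transcription factor genes of stress responses, fell by 2.93, 2.77, 2.54 and 2.41 on the log2 scale (SE 0.25, 0.43, 0.34 and 0.26, limma adjusted p = 0.000488, 0.00552, 0.00302 and 0.00117). WRKY40 averaged 9.29 ± 5.22 FPKM in Col-0 and 0.815 ± 0.423 in cnd1-3, ZAT10 33.3 ± 11.6 and 5.4 ± 2.49, and ERF5 10.9 ± 3.1 and 1.65 ± 0.652. Also past the test, and named after their values were seen, were 3 more members. BAP1 fell from 6.44 ± 2.38 to 0.836 ± 0.0585 FPKM, the glucosyltransferase gene UGT74E2 rose from 0.819 ± 0.513 to 2.67 ± 0.0573 FPKM (1.33, SE 0.24, adjusted p = 0.0111) and the iron storage gene FER1 from 23.3 ± 3.62 to 50.1 ± 9.28 (1.09, SE 0.14, adjusted p = 0.00288). WRKY40 and FER1 overlap another gene on the opposite strand. The set test, which averages over members that moved apart, did not pass (camera adjusted p = 0.646). The 5 genes that fell, like ORA47 and CBF1 above, belong to a list of touch, wound and cold genes drawn up after the data were seen, whose mean log2 value varied by 0.81 between Col-0 libraries and by 0.72 between cnd1-3 libraries.

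Hormone and defence genes changed individually, and none of their lists passed as a set. Of 11 tested salicylic acid and defence genes 1 rose and 2 fell, also when adjusted over the list alone. PR5, a pathogenesis-related protein gene, rose from 8.52 ± 0.138 to 14.5 ± 4.11 FPKM (log2 fold change 0.69, SE 0.18, limma adjusted p = 0.0434). WRKY70, a defence regulator, fell from 44.6 ± 5.71 to 28.8 ± 3.7 (-0.62, SE 0.12, adjusted p = 0.0132) and PBS3, which acts in salicylic acid synthesis, from 1.79 ± 0.326 to 0.839 ± 0.154 (-0.77, SE 0.16, adjusted p = 0.0213). Of 6 tested jasmonate genes 2 fell and 0 rose, and 3 fell when adjusted over the list alone. JAZ1, a repressor of jasmonate signalling that jasmonate induces, is 1 of the touch, wound and cold genes described above and fell from 13.8 ± 4.43 to 2.53 ± 1.15 FPKM (-2.26, SE 0.28, adjusted p = 0.00213) and OPR3, a jasmonate synthesis gene, from 13 ± 2.16 to 8.64 ± 1.54 (-0.57, SE 0.14, adjusted p = 0.0386). Of 11 tested genes of abscisic acid and cold 2 fell and 1 rose, and 4 fell and 1 rose when adjusted over the list alone. The dehydrin gene ERD10 fell from 122 ± 11.7 to 65.7 ± 9.31 FPKM (-0.89, SE 0.11, adjusted p = 0.002), the phosphatase gene ABI1 from 19.6 ± 3.02 to 12.2 ± 2.02 (-0.66, SE 0.14, adjusted p = 0.0208), and the related HAI1 rose from 0.576 ± 0.174 to 1.23 ± 0.156 (0.69, SE 0.18, adjusted p = 0.0406). The camera adjusted p values of the 3 lists were 0.493, 0.421 and 0.44. Without cnd1-3 replicate 3 the jasmonate list passed at 0.0401 and the list of abscisic acid and cold at 0.0199, both lower. PR5 kept its call only without cnd1-3 replicate 2 (adjusted p = 0.0028) and HAI1 only without Col-0 replicate 2 (0.0436). Without Col-0 replicate 2, OPR3, PBS3, ABI1 and WRKY70 lost theirs (0.115, 0.0733, 0.0761 and 0.0557). OPR3, PBS3 and ABI1 also did without cnd1-3 replicate 1 (0.122, 0.0531 and 0.0675), OPR3 and ABI1 without cnd1-3 replicate 2 (0.112 and 0.0588), PBS3 without cnd1-3 replicate 3 (0.0635), and OPR3 and PBS3 without Col-0 replicate 1 (0.0663 and 0.0519). With no minimum level PR5 and OPR3 did not pass (0.0828 and 0.0729), nor without the intensity trend (0.0739 and 0.0659), and PR5 also not with robust fitting (0.0562) or library weights (0.0506). ABI1 overlaps another gene on the opposite strand.

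Glucosinolate synthesis genes, which make sulfur-rich defence compounds of the cabbage family, were lower in cnd1-3 as a set by camera at its preset correlation (adjusted p = 0.0242). The same list had an adjusted p = 0.896 with an estimated correlation and 0.254 by fry, and it did not pass without cnd1-3 replicate 1 (0.0655), cnd1-3 replicate 2 (0.193) or Col-0 replicate 3 (0.0684). As for the tetrapyrrole list, splits that mix the genotypes gave up to 9 called lists against 2, so the set call alone does not tie this list to the genotype. Of 13 tested members 6 fell, 0 rose and 7 did not pass, and 8 fell when adjusted over the list alone. The regulator genes MYB34, MYB29 and MYB28 fell from 18.3 ± 2.2 to 10.9 ± 0.998 FPKM (log2 fold change -0.72, SE 0.10, limma adjusted p = 0.00432), from 7.49 ± 1.51 to 4.46 ± 0.916 (-0.69, SE 0.17, adjusted p = 0.0345) and from 39.8 ± 3.77 to 29.5 ± 4.48 (-0.43, SE 0.11, adjusted p = 0.0452). The cytochrome P450 gene CYP79B3 of the tryptophan-derived branch fell from 11.2 ± 0.475 to 6.9 ± 0.634 (-0.66, SE 0.09, adjusted p = 0.00287). The list had a median log2 fold change of -0.40. Without cnd1-3 replicate 1, cnd1-3 replicate 2 or Col-0 replicate 1, 3 members fell, and without Col-0 replicate 2, 2 fell. MYB28 kept its call only without cnd1-3 replicate 3 (adjusted p = 0.0168), and MYB29 only without cnd1-3 replicate 3 and Col-0 replicate 3 (0.0329 and 0.0301). In 6 other alternatives MYB28 did not pass, up to 0.0807 without the intensity trend, and MYB29 did not with no minimum level (0.0707) or without the trend (0.0575).

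Of 4 tested phosphate starvation genes 3 fell in cnd1-3, and 3 fell and 1 rose when adjusted over the list alone. SPX1, a sensor of phosphate status, fell from 10.9 ± 2.17 to 6.34 ± 0.87 FPKM (log2 fold change -0.73, SE 0.15, limma adjusted p = 0.0161). The acid phosphatase gene PAP17 fell from 3.34 ± 1.47 to 1.34 ± 0.224 (-0.99, SE 0.27, adjusted p = 0.0486) and SRG3, a glycerophosphodiester phosphodiesterase gene, from 1.57 ± 0.197 to 0.833 ± 0.168 (-0.64, SE 0.16, adjusted p = 0.0358). Of 7 tested iron deficiency genes 0 passed limma's test, 4 had an unadjusted p under 0.05 and 4 fell when adjusted over the list alone, while voom called 0. The 7 log2 fold changes were all below 0 in that fit, with BHLH100 at 4.35 ± 1.51 FPKM in cnd1-3 and 9.59 ± 4.4 in Col-0 (adjusted p = 0.118) and IMA3 at 10 ± 1.39 and 14.1 ± 3.04 (adjusted p = 0.0876). The iron list did not pass as a set (camera adjusted p = 0.164) but did without cnd1-3 replicate 3 (0.0411) and without Col-0 replicate 1 (0.00261), where 4 members were lower. Of 4 tested genes of anthocyanin and flavonol synthesis the chalcone synthase gene CHS fell from 9.51 ± 2.83 to 4.79 ± 0.442 FPKM (-0.88, SE 0.19, adjusted p = 0.0236), with 2 lower and 1 higher when adjusted over the list alone. PAP17, SRG3, IMA3 and CHS each overlap another gene on the opposite strand. PAP17 kept its call only without Col-0 replicate 1 (adjusted p = 0.00547), SRG3 only without cnd1-3 replicate 3 (0.0451), with highest values of 0.142 and 0.118. In 8 other alternatives PAP17 did not pass, up to 0.0925 with no minimum level, and SRG3 did not under quantile normalization (0.0609). CHS kept its call only without cnd1-3 replicate 3 and Col-0 replicate 1 (0.0428 and 0.00234) and did not pass with no minimum level (0.0543). SPX1 lost its call without cnd1-3 replicate 1 (0.0528).

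**Figure D3:**
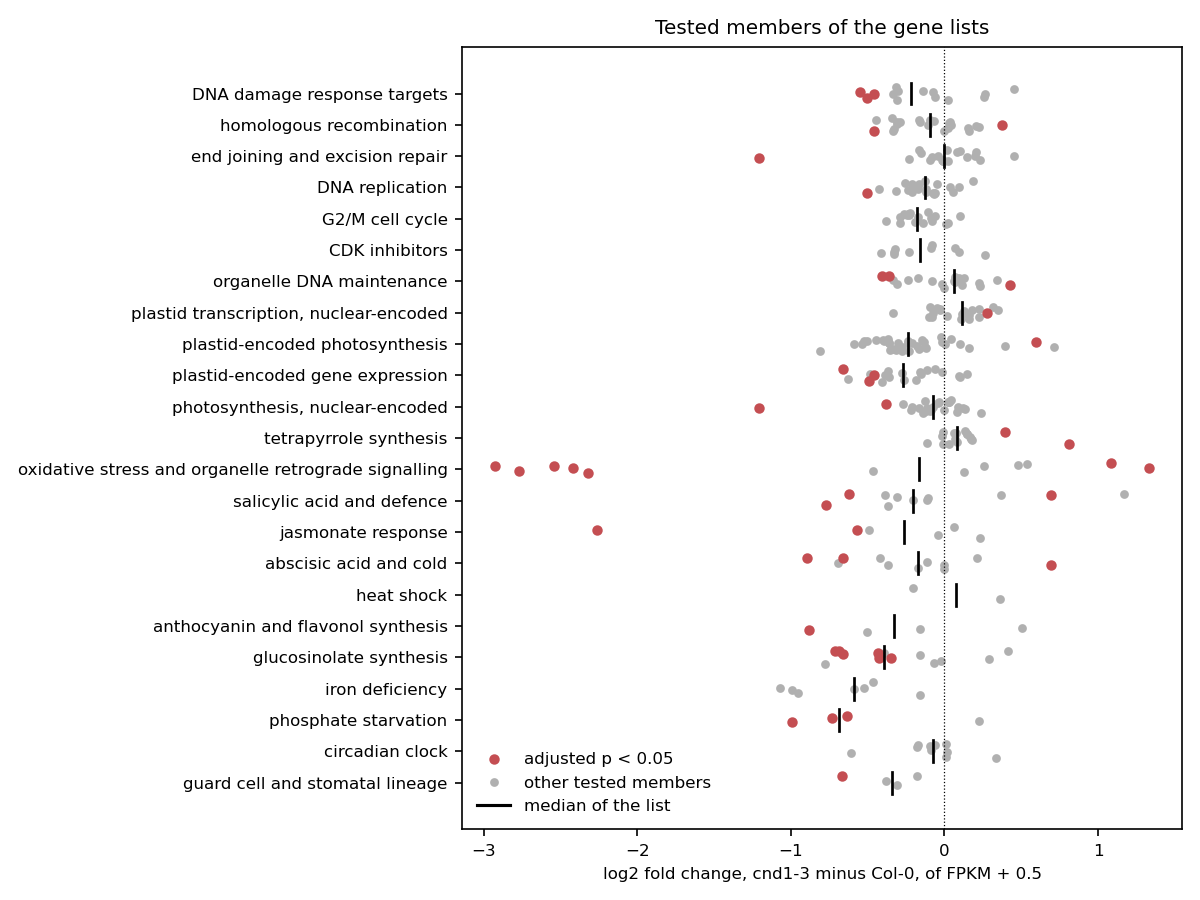
Log2 fold change (cnd1-3 minus Col-0, of FPKM plus 0.5) of each tested member of the 23 lists with tested members, with members past the adjusted threshold in red, the others in grey and a black line at the median of each list. The 5 red points furthest to the left of the oxidative stress list lie between -2.93 and -2.32, and the medians of the tetrapyrrole and glucosinolate lists lie at 0.08 and -0.40.

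The circadian clock list, which would move with the hour of harvest, had 0 of 10 tested genes past limma's test, 2 at an unadjusted p under 0.05 and 0 when adjusted over the list alone, while voom called 1 higher and 1 lower. TOC1 averaged 83.7 ± 0.639 FPKM in cnd1-3 and 89.1 ± 2.56 in Col-0, and ELF4 averaged 129 ± 12.5 and 145 ± 4.16 (camera adjusted p = 0.687). Of the heat shock list 2 members were tested and 0 changed, with 0 at an unadjusted p under 0.05, 0 by voom and 0 when adjusted over the list alone. HSP101, which overlaps another gene on the opposite strand, averaged 4.65 ± 0.413 FPKM in cnd1-3 and 5.43 ± 0.343 in Col-0, and HSFA2 averaged 1.97 ± 0.469 and 1.45 ± 0.568. Among markers of organs and cell types, 0 of 15 root markers and 0 of 12 seed storage and late embryogenesis genes reached the minimum level. The highest value of any root marker in any library was 0.291 FPKM, and that of any seed marker 0.122. By these markers the libraries held almost no root RNA. The results above, those on DNA damage and the cell cycle among them, therefore say little about roots. CASP4 lay at 0.0881 and 0.175 FPKM in cnd1-3 and Col-0, WOX5 at 0.0698 and 0.175, SESA2 at 0.0407 and 0.0195, and CRU1 listed at 0. Of 4 tested guard cell and stomatal genes the potassium channel gene KAT1 fell from 10 ± 1.74 to 6.08 ± 0.328 FPKM (log2 fold change -0.67, SE 0.12, limma adjusted p = 0.0114), also when adjusted over the list alone.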

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

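Of 57 called genes named by the rule, 25 kept the call under every alternative in which they were tested (up to 21 each, treat not among them), 32 lost it at least once, and no log2 fold change of a called gene reversed. Among them MAF5, MAF4, QQS, XRCC4, LHCB1.1, PORA, ZAT12 and JAZ1 kept theirs. BHLH100 and IMA3, not called, passed at least once. The 12 called genes named outside the rule in the report and the observations kept theirs wherever tested, UGT74E2, like MAF4, lying below a minimum of 2 FPKM. The number of changed genes, 1896, stayed within 1473 (no minimum level) and 2143 (voom) under changes of pseudocount, level, scaling, variance model, weights, depth and GC or length. It was 107 with treat, which asks for more than a log2 fold change of 0.58 by construction, and 906 to 1848 with a library left out, where fewer samples were tested. With the replicate block it was 2879, and with the block and the GC and length trend removed 2993; the cause was not tested. The labels state no pairing by replicate number. Residual correlations between samples of the same number were 0.03, 0.16 and 0.26. Replicates 2 and 3 of cnd1-3 correlated best with Col-0 of their own number, and replicate 1 with Col-0 replicate 2 (0.08). The second principal component (14.4% of the variance) was 5.01, 11.47 and -13.37 in cnd1-3 replicates 1 to 3. In Col-0 replicates 1 to 3 it was 3.7, 12.07 and -18.88. Whether the numbers mark a shared batch cannot be told from the labels. Changes of at least 2-fold, 338, ranged from 238 to 489, and from 278 to 368 with a library left out. The number of lists called, 2, was 4 with median-ratio scaling, 1 with quantile normalization, 4 with the replicate block, 0 with an estimated correlation and 0 with fry, and 1 to 6 with a library left out; the cause was not tested. At the depth of the shallowest library 1798 genes changed.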

Other observations

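Beyond the fixed lists, 8 groups of genes were examined, all chosen after seeing the data. Their counts and camera p-values therefore describe these data and are no independent tests. Some groups hold genes already named for their large changes, such as MAF4 and MAF5 in the FLC clade. Genes that respond within minutes to touch, wounding and cold had the largest median change of these groups. Of 33 tested members 20 fell and 0 rose, with a median log2 fold change of -1.44 (camera adjusted p = 1.66e-12, and 0.222 with an estimated correlation), and 9 members were shared with the fixed lists. CBF2 and CBF3, neighbours of CBF1 in the cold response, fell by 2.44 and 1.99, the ethylene response factor gene ERF6 by 2.79, and CAF1A, a deadenylase gene, from 106 ± 23 to 17 ± 5.55 FPKM. Not all touch genes followed: TCH4 averaged 30.9 ± 21.1 FPKM in cnd1-3 and 32.7 ± 13.4 in Col-0. Genes of dark and sugar starvation rose, 8 of 13 tested with 0 lower (camera adjusted p = 1.87e-08, and 0.105 with an estimated correlation), among them DIN10, from 20.8 ± 1.42 to 57.6 ± 19.4 FPKM, and BT2, from 43.6 ± 2.68 to 72.4 ± 1.53. Without Col-0 replicate 2 the count was 3, and without cnd1-3 replicate 1 it was 5.

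Of 38 tested core histone genes 9 fell, 0 rose and 29 did not pass, with 36 log2 fold changes below 0 (camera adjusted p = 4.8e-07, and 0.304 with an estimated correlation). HTA4 fell from 12.7 ± 1.14 to 5.82 ± 0.668 FPKM. The count of falls was 1 without cnd1-3 replicate 1 or 3 or Col-0 replicate 1 or 2, and 18 without Col-0 replicate 3. It was 4 with no minimum level, 2 without the intensity trend and 14 with the GC and length trend removed. With the replicate block it was 25, and with the block and that removal 24. All 16 tested mitochondrial genes had log2 fold changes below 0, with 7 called (camera adjusted p = 0.000187, and 0.203 with an estimated correlation), in poly(A)-selected RNA. The count was 2 without cnd1-3 replicate 1, 4 without cnd1-3 replicate 3 and with voom, 3 at a minimum of 2 FPKM, and 3 without Col-0 replicate 1 or 2. Of 95 tested NBS-LRR disease resistance genes 11 fell and 1 rose (camera adjusted p = 0.00313, and 0.222 with an estimated correlation). The falls numbered 4 without any of the cnd1-3 libraries in turn, 5 without Col-0 replicate 1 and 6 without Col-0 replicate 3. With quantile normalization 5 fell and 2 rose, with the GC and length trend removed 6 and 2, with no minimum level 6 and 0, and with voom 18 and 1. That list did not pass without cnd1-3 replicate 2 (0.0535), without Col-0 replicate 3 (0.0525) or with the GC and length trend removed (0.0508). Of 45 tested photosystem and light-harvesting subunit genes 1 rose and 2 fell, while the set test pointed up, with 30 log2 fold changes above 0 and a median of 0.08 (camera adjusted p = 0.00551, and 0.409 with an estimated correlation). The list did not pass under quantile normalization (0.423), with the GC and length trend removed (0.0508) or without Col-0 replicate 2 (0.218). Its rises numbered 4 without Col-0 replicate 3 and 0 without each other library in turn, and its falls 1 without any library but cnd1-3 replicate 3. The rises numbered 5 with the replicate block and 6 with the block and the GC and length trend removed. They numbered 3 under median-ratio scaling, quantile normalization, removal of the GC and length trend, library weights and voom. At a minimum of 2 FPKM and with robust fitting they numbered 2, and without the intensity trend 0. The falls numbered 1 with voom and at a minimum of 2 FPKM. Of 5 tested genes of the FLC clade MAF1, MAF4 and MAF5 fell and 0 rose (camera adjusted p = 0.000656, and 0.105 with an estimated correlation), with 1 higher when the GC and length trend was removed. Of 4 tested floral integrator genes SOC1 rose and 0 fell. In this group 2 were higher under median-ratio scaling, quantile normalization, removal of the GC and length trend, library weights and voom. The same number was higher without Col-0 replicate 2 and with the replicate block, alone or with the GC and length trend removed.

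Of the tests below, the range of the touch list within genotypes, the genes between FLC and MAF5 and the count of near-silent genes had predictions written before their values were computed. The tests of depth, clock genes, SOC1 and scaling were chosen only after the result was seen.

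The fall of touch, wound and cold genes could come from handling at harvest rather than from the genotype. The mean log2 value of the list was 2.42, 1.7 and 2 in the cnd1-3 libraries and 3.1, 3.9 and 3.67 in Col-0, a difference of -1.51. Its range was 0.81 over the Col-0 libraries and 0.72 over the cnd1-3 libraries. Both ranges lay at percentile 100 of those of 10000 random lists matched on expression. The prediction for no handling effect, ranges no wider than those of most matched lists, therefore failed. The matched lists held random genes, however, whereas this list was gathered from genes that respond to the same stimuli. Such genes can vary together with or without handling, so the wider ranges decide nothing about it. The prediction for handling, ranges as large as the difference between the genotypes, was not met either. Handling and genotype cannot be told apart here, since the labels do not say how or in what order the seedlings were harvested. With reads thinned to the shallowest library the median was -1.45. Thinning keeps the expected FPKM of each gene, so this argues only against an effect of sampling fewer reads. Another hour of harvest cannot be told apart from the genotype either: the largest absolute log2 fold change of the clock genes was 0.61, but voom called 1 of them higher and 1 lower.

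The near absence of reads on FLC, MAF4 and MAF5 might reflect regulation or the genome of the line. A single missing segment that spans FLC to MAF5 is argued against by the 98.1% of 3081 tested genes between them that lay within 2-fold. That value says nothing of smaller losses, at FLC alone or at the adjacent MAF4 and MAF5, which were not tested. Sequence variants that keep reads from being placed cannot be told apart from lost expression: 11 genes with at least 10 reads in every Col-0 library had at most 3 in cnd1-3. Of these, FLC, AT1G78750 and AT5G27340 had 0. The other way, 0 genes had 0 reads in Col-0 and at least 10 in every cnd1-3 library. That count compares only with the 3 genes at 0 in cnd1-3, since the limit of at most 3 reads was not applied to Col-0. SOC1, which FLC represses, rose by 0.60, as a loss of repressors would give. Since SOC1 was picked after its rise was seen, this is no independent test of such a loss.

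Of all calls 68.5% were lower with the FPKM as deposited and 54.3% under median-ratio scaling, which sets the median log2 fold change near 0 by construction (0.001, against -0.051) and so fixes a nearly even share of small calls. For these, scaling and a real excess of falls cannot be told apart. Among calls of at least 2-fold 72.3% were still lower under that scaling, and 66.1% under quantile normalization. Median-ratio scaling moved the median by only 0.052, too little to even out changes of 2-fold. The share argues only against a shift of that size as the cause of the excess there. With thinned reads the share of all calls was 69.2%, which argues only against an effect of unequal read numbers on which genes were called. No biological explanation of the excess was tested.

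The 6 libraries can be divided into 10 splits of 3 against 3, too few for a small share. The split by genotype gave 1896 changed genes and 338 of at least 2-fold, and the highest count of any other split was 0 for each, so that 1 split, the real one, was as large. For lists called the genotypes gave 2, and another split gave 9, with 9 of the 10 splits, the real one among them, as large. The number of lists called by camera at its preset correlation therefore does not set the genotypes apart from other splits.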
